A study of Rattus norvegicus with 15 samples.

How the data were processed

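Messenger RNA of the dorsal CA1 area was sequenced from 15 samples of male Sprague-Dawley rats aged 8 to 9 weeks, 5 in each of 3 groups. The tissue was frozen and held all brain cell types, per the labels. Libraries were made with a stranded messenger RNA kit and 14 cycles of PCR, per the labels' protocols. Trim Galore, FastQC, featureCounts 2.0.1, DESeq2 and the genome build Rnor_6.0 are named in the submitters' processing notes. The aligner, the annotation release, the strand setting of the counting and any filter on low counts are not given in the sources used here. Without the strand setting, reads of overlapping genes on opposite strands cannot be assigned with certainty.

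The authors deposited a table of raw counts per gene symbol, with 16945 genes and 1 column per sample, and the smallest row total over the 15 samples was 64. The deposited second table holds a normalized signal, the same counts divided by 1 size factor per sample. In all 15 samples the ratio of the 2 tables was constant within a relative tolerance of 1e-10, and DESeq2 gave the same size factors when run on the counts. Every column was matched to its sample by the name given in the sample description. The normalized table was used only for that check. Symbols were compared with the RefSeq table of the assembly GRCr8, which differs from the build of the counts and served for names only: 14446 symbols were found, 419 were older symbols and 2080 were not found. The files give no coordinates, so genes are named without positions. Names such as AC125248.1 are clone-based, and 1531 genes have such a name.

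Groups were taken from the sample titles. No library batch and no time between training and dissection was used, since the labels give neither. There was no group of Psmc5 siRNA without training, so an interaction of siRNA and training was not tested. The comparisons were trained against naive under control siRNA, Psmc5 siRNA against control siRNA in trained rats, and Psmc5 siRNA in trained rats against naive rats with control siRNA. All 15 libraries entered 1 fit with no covariate.

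Genes with low counts were removed with filterByExpr of edgeR (minimum count 10, minimum total 15), which left 16272 genes and removed 673. Library sizes were scaled by TMM. Dispersions were estimated robustly, and genes were tested with edgeR 4.0.16 by the quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The SE of a log2 fold change was set so that the squared ratio of the change to its SE equals the F statistic. Log2 fold changes and SEs are from edgeR throughout, also for genes called by DESeq2. CPM values are counts per 1e6 counts of the TMM-scaled library, computed from the deposited counts, and log2 CPM used a prior count of 1. DESeq2 1.42.0 and limma 3.58.1 were the other tools, run under R 4.3.3. DESeq2 gave no adjusted p for 7 genes, which were left out of its counts.

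Choices made before the data were examined were the 40 gene lists with 889 genes, the tests, the rule for named genes and most of the other settings. Of the list genes 815 were tested. Lists were tested with camera on voom values at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the 40 lists. Camera compares a list with all other genes, while fry asks whether a list's genes move on balance in 1 direction. Each list's mean log2 CPM per library was also compared by an exact two-sided permutation test over all 252 regroupings of 5 against 5. Its smallest possible p is 0.00794, which for 1 list alone comes to 0.317 after adjustment over the 40 lists. This permutation test could therefore call no list unless several reached that p together. "Adjusted over the list alone" means Benjamini-Hochberg adjustment of the edgeR p-values of that list's tested genes.

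The rule named Psmc5 in every sample. In each comparison it named up to 12 genes with the largest change in each direction among those past the threshold with a mean of at least 1 CPM and at least 4 of the 5 libraries of the first group beyond the median of the second, or, where fewer than 5 passed, the 10 genes with the smallest p. In each list it named up to 4 members with the smallest p and any member past the threshold. The text gives a part of the members so named.

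Libraries held 37.8e6 to 54.4e6 counts, and the median SE of a log2 fold change was 0.139, 0.138 and 0.139 in the 3 comparisons in the order above. The fit was tested on simulated counts with the real means, dispersions and library sizes and 200 changed genes per comparison. Each gene was drawn independently of the others. For trained against naive, genes changed 1.25-fold were called in 2% of cases, 1.5-fold in 44%, 2-fold in 64% and 4-fold in 86%, and 5 of the 103 calls were false. For Psmc5 siRNA against control siRNA in trained rats the shares were 8%, 40%, 56% and 94%, with 3 of 102 calls false. For Psmc5 siRNA trained against naive they were 2%, 38%, 68% and 90%, with 3 of 102 calls false. A list of immediate early genes shifted by 0.3 (log2) in simulated trained libraries was recovered by camera, and 0 of the 39 other lists were called. Since genes were independent there, this does not show how often camera calls lists when genes are correlated. In other splits of the real trained control and naive libraries camera called up to 27 lists.

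The other settings chosen beforehand were DESeq2, voom without and with sample quality weights, DESeq2 size factors, library totals only, no filter, at least 1 CPM in 5 samples, the 2 compared groups alone, the first principal component of the cell type list genes or 1 surrogate variable (sva 3.50.0) as a covariate, each library left out in turn, an adjusted p under 0.1 and a minimum of 1.5-fold. Settings chosen after seeing the data were the mean of the reactive astrocyte or the choroid plexus list as a covariate, the exact permutation of list means, and 2 sets of libraries left out. The first set held the 4 libraries with a score above 30 on the first principal component (trained control replicates 15 and 10, Psmc5 siRNA replicates 13 and 7). The second set held the 2 trained control libraries with a Ttr level under 100 CPM (replicates 16 and 5).

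Comparisons that share a group were set against 20 simulations without any effect, against 100 relabelings of the 15 libraries and against 20 splits of the shared group. Genes were drawn independently in these simulations, so their spread leaves out the correlation between genes. For each count by edgeR or camera, 100 of the 126 splits of the 10 libraries compared were drawn, the real one included. DESeq2 was not run on these splits.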

Results

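Gene expression was measured by sequencing messenger RNA from the dorsal CA1 area of the rat hippocampus, a region needed for memory of places and contexts. Male rats received an injection of small interfering RNA (siRNA, a short RNA that directs the breakdown of a matching messenger RNA) and were trained 5 days later in contextual fear conditioning, in which an animal learns to fear a chamber where it was shocked. The siRNA was either a scrambled control or matched Psmc5, the gene of RPT6, which is an ATPase subunit of the 19S regulatory particle of the proteasome. There were 3 groups of 5 libraries each: control siRNA and no training (naive), control siRNA and training, and Psmc5 siRNA and training. The libraries held 37.8e6 to 54.4e6 counts, and 16272 of the 16945 genes in the table were tested. Pairs of libraries within a group differed by up to 218 chi-square units per degree of freedom and by no fewer than 25, so no library was a near-copy of another of its group. The labels number the samples but do not state that each came from a separate animal, so p-values measure the spread between these libraries.

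Psmc5 RNA was the first check of the labels, and it was at the same level in all 3 groups. It stood at 158 ± 17.8 CPM (counts per 1e6 counts; SD, n = 5) in the Psmc5 siRNA libraries, at 160 ± 22.0 in trained libraries with control siRNA and at 162 ± 8.08 in naive libraries. The 5 Psmc5 siRNA libraries had 182, 156, 170, 137 and 147 CPM, and the 5 trained controls had 145, 196, 144, 149 and 166 CPM. Against the trained controls the log2 fold change of Psmc5 was -0.01 ± 0.10 (SE), and the exact two-sided permutation test of log2 CPM over all regroupings gave p = 0.944. The 95% interval of the fold ran from 0.857 to 1.14, so a loss of Psmc5 RNA of more than 14.3% in the whole tissue lay outside it. "Psmc5 siRNA" therefore stands for the label of a library, and the direction of every comparison with these libraries rests on that label.

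**Figure D1:**
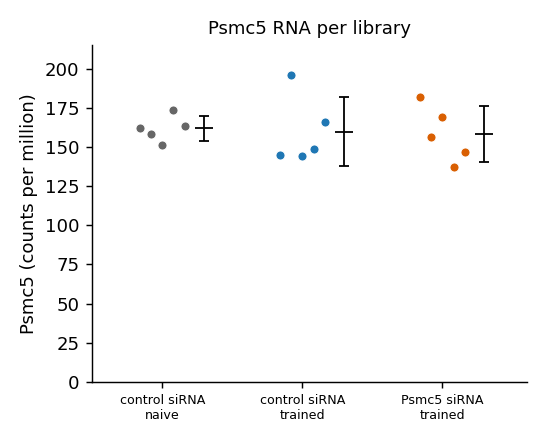
Psmc5 RNA in CPM (vertical axis, from 0) for each library of the 3 groups; each point is 1 library, and the bar beside the points is the mean with its SD (n = 5). The Psmc5 siRNA libraries lie between 137 and 182 CPM and overlap the trained controls, which lie between 144 and 196 CPM.

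The first comparison asked what training changed under control siRNA. Trained libraries had higher RNA of Junb and Egr2, transcription factors of the immediate early class that neuronal activity induces, and of Per1 and Ddit4, both targets of the glucocorticoid receptor. Junb had a log2 fold change of 0.63 ± 0.13 (SE) and rose from 32.1 to 49.9 CPM, and Egr2 had 1.79 ± 0.39. Per1 had 0.71 ± 0.15 and Ddit4 0.46 ± 0.09. All 5 trained libraries lay above the naive median for each of these 4 genes, which their choice by a small p makes likely. Lower values were seen for Slc22a8, an organic anion transporter of brain barriers (-0.61 ± 0.11), for Capn5, a calcium-dependent protease (-0.33 ± 0.06), and for Kdr, the main VEGF receptor of endothelial cells (-0.50 ± 0.11). By DESeq2, 23 genes rose and 29 fell, and the 7 genes named here were among them. How many genes DESeq2 calls in other splits of these libraries was not measured. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, no gene passed: 0 of 16272 had an adjusted p under 0.05, and the smallest was 0.326. With limma voom 0 genes passed, with or without sample quality weights. At an unadjusted edgeR p under 0.05 there were 1709 genes, 1078 higher and 631 lower in trained libraries, where 813.6 would be expected with no difference.

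The other genes among the 10 smallest edgeR p-values, none past the edgeR threshold and all called by DESeq2, were the clone-named AC125248.1 (log2 fold change 3.22 ± 0.62, from 0.446 to 4.16 CPM) and AABR07007032.1 (-0.30 ± 0.06), B3gnt2, a glycosyltransferase (0.45 ± 0.09), Tmc7 (-0.53 ± 0.10), Susd5 (-0.69 ± 0.14) and Spock1, an extracellular proteoglycan (-0.52 ± 0.11). B3gnt2 alone passed edgeR's test without trained control replicates 16 and 5, 2 libraries with few choroid plexus transcripts (adjusted p = 0.0267), and over all settings its adjusted p ran from 0.00322 with DESeq2 to 0.813. Without trained control replicate 10 the only gene past the edgeR threshold was Reck, named after its value was seen (-0.70, adjusted p = 0.0329).

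**Figure D2:**
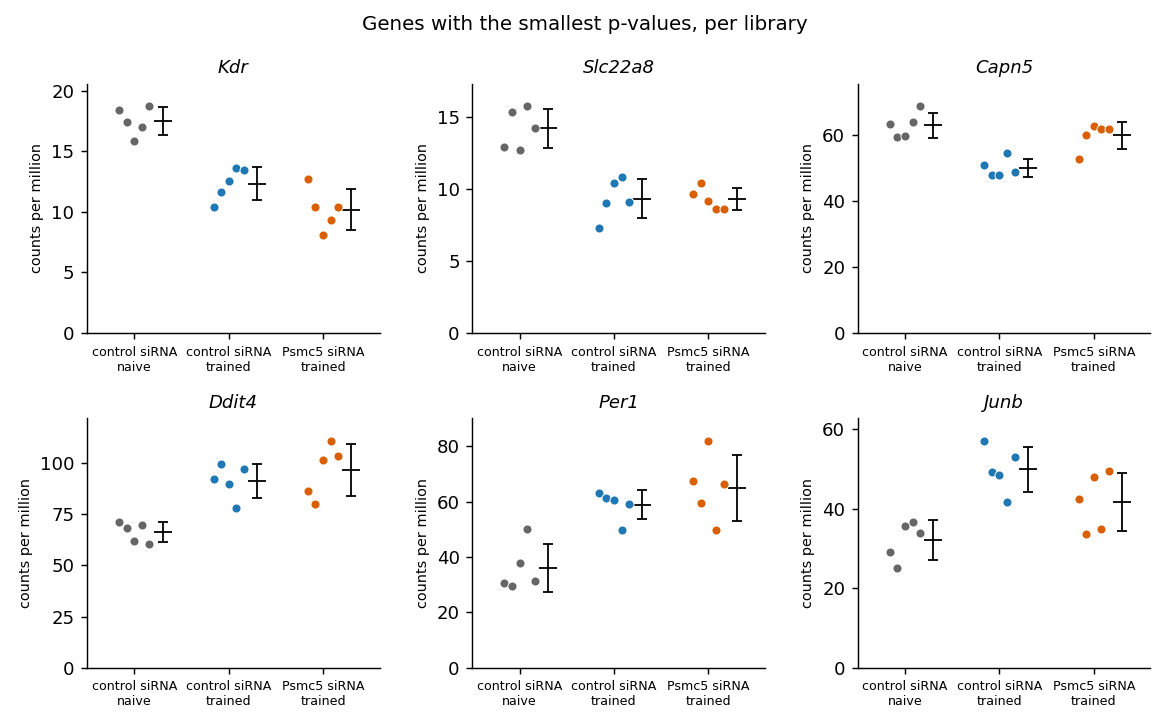
CPM (vertical axes, from 0) of 6 genes in each library of the 3 groups; points are libraries, and the bars beside them give the mean and SD (n = 5). Kdr and Slc22a8 are lower and Ddit4 and Per1 higher in both trained groups than in naive libraries, Capn5 is lower in the trained controls at 50.1 CPM against 63.1 CPM, and Junb is higher there at 49.9 CPM against 32.1 CPM.

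Of the 40 gene lists fixed before the data were examined, 15 rose and 8 fell with training by camera at its preset correlation of 0.01. With an estimated correlation 0 lists kept an adjusted p under 0.05, by fry 0 did, and 5 and 8 lists had an unadjusted p under 0.05 in these 2 tests. All 13 measured genes of the 20S proteasome core, the chamber in which proteins are degraded, had higher means in trained libraries (median log2 fold change 0.18; adjusted p = 0.360 with an estimated correlation). Adjusted over the list alone, 5 of these genes rose, among them Psmb2 (0.25 ± 0.06) and Psma5 (0.24 ± 0.07). The list mean was 6.64 ± 0.11 log2 CPM in trained and 6.48 ± 0.04 in naive libraries (n = 5 each), with no overlap. Its exact permutation p was 0.00794, the smallest that groups of 5 can give, and 0.106 after adjustment over the 40 lists. The 19S regulatory particle, to which RPT6 belongs, had 18 of 19 genes higher with a median of 0.10, and 0 passed when adjusted over the list alone (adjusted p = 0.378 with an estimated correlation). Its member with the smallest p was Psmc4 (0.21 ± 0.06).

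Immediate early genes had 31 of 38 members higher, with a median log2 fold change of 0.33 (adjusted p = 0.360 with an estimated correlation). Junb and Egr2 rose when adjusted over the list alone, and Atf3, a stress-induced member, had 2.16 ± 0.68 without passing (1.55 without trained control replicate 15). The lowest trained library, at 3.97 log2 CPM over the list, lay above the highest naive one at 3.96 (exact permutation p = 0.00794, 0.106 adjusted over the lists). Heat shock and protein folding genes had 22 of 23 members higher with a median of 0.09 (adjusted p = 0.360 with an estimated correlation). Adjusted over the list alone, 4 of them rose: Hmox1, the inducible heme oxygenase (3.41 ± 0.97), Hspb1 (2.32 ± 0.65), Hspa1b (1.69 ± 0.50) and Dnajb1 (0.33 ± 0.08). Hmox1 differed between the trained libraries, with 1128, 449 and 829 CPM in replicates 15, 16 and 10 but 27.8 and 62.8 CPM in replicates 6 and 5, against a naive mean of 46.8 CPM. Replicates 15 and 10 stood apart on the first principal component, to which Hmox1 contributed. Without the 4 libraries apart on that component Hmox1 had 1.94, Hspb1 1.54, Hspa1b 0.76 and Dnajb1 0.34. Hspa1b has a near-identical copy, so its count is uncertain. Glucocorticoid response genes had 18 of 23 members higher with a median of 0.35 (adjusted p = 0.360 with an estimated correlation), and Per1 and Ddit4 passed when adjusted over the list alone. Cytosolic ribosomal protein genes had 58 of 61 members higher with a median of 0.19, of which 0 passed when adjusted over the list alone (adjusted p = 0.521 with an estimated correlation). Rps2 had 0.33 ± 0.13, and counts in this family can be shared with processed pseudogenes.

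Lists of inflammation and of blood also rose by camera. Reactive astrocyte genes had 18 of 18 members higher with a median of 1.12, and 10 passed when adjusted over the list alone, among them Gfap, the astrocyte filament protein (0.77 ± 0.26), Timp1 (2.46 ± 0.62) and Lgals3 (2.44 ± 0.75). Replicates 15 and 10, which stood apart on the first principal component, had the highest list means of the trained controls (5.45 and 4.89), while replicate 5 had 3.32. Without the 4 libraries apart on that component Timp1 had 1.78 and Lgals3 1.36. The adjusted p was 0.378 with an estimated correlation, and the list mean was 4.44 ± 0.86 log2 CPM in trained and 3.42 ± 0.20 in naive libraries (n = 5; exact permutation p = 0.0635). Interferon response genes had 32 of 32 members higher with a median of 1.10, and 7 passed when adjusted over the list alone, among them Irf9 (0.70 ± 0.16), Isg15 (1.63 ± 0.46), Usp18 (1.76 ± 0.54) and Mx2 (2.03 ± 0.64). The adjusted p was 0.378 with an estimated correlation, and the list mean was 5.05 and 4.34 log2 CPM in replicates 15 and 10, which stood apart on the first principal component, against 3.86, 3.45 and 2.34 in replicates 16, 6 and 5. Without the 4 libraries apart Irf9 had 0.51, Isg15 0.80, Usp18 0.72 and Mx2 0.88. Blood cell genes, mostly hemoglobins, had 6 of 6 members higher and all 6 passed when adjusted over the list alone (median 2.07; adjusted p = 0.360 with an estimated correlation). Hba-a2 had 2.29 ± 0.66 and Hbb 2.00 ± 0.66, and the hemoglobin copies can share reads. Infiltrating immune cell genes had 13 of 13 members higher with a median of 1.16, and S100a9 (2.75 ± 0.74) passed when adjusted over the list alone (adjusted p = 0.378 with an estimated correlation). Among the trained controls Mrc1 of this list was highest in replicates 15 and 10 (22.5 and 15.8 CPM), as was Lgals3 (199 and 183 CPM). Which cells held the RNA of the reactive astrocyte list was not measured.

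Genes of synapses and of excitability fell as lists, by small amounts. Presynaptic vesicle genes had 27 of 27 members lower with a median of -0.21, and 0 passed when adjusted over the list alone (adjusted p = 0.422 with an estimated correlation). Rims1, an active zone scaffold, had -0.40 ± 0.15, and Syn1, a synaptic vesicle protein, had -0.31 ± 0.12. The list means of replicates 15 and 10, which stood apart on the first principal component, were the lowest of the trained controls (7.79 and 7.70 log2 CPM), while replicates 6 and 5 (8.17 and 8.26) lay within the naive range of 8.09 to 8.38. Without the 4 libraries apart Rims1 had -0.27 and Syn1 -0.15. Voltage-gated ion channels had 31 of 33 members lower with a median of -0.17, and 0 passed when adjusted over the list alone (adjusted p = 0.521 with an estimated correlation). Kcnq5 had -0.40 ± 0.12 and Kcna2 -0.33 ± 0.13 (-0.29 and -0.16 without the 4 libraries). This list was at 6.02, 6.00 and 5.94 log2 CPM in replicates 15, 16 and 10, under the lowest naive library at 6.20, and at 6.58 and 6.44 in replicates 6 and 5. Oligodendrocyte genes had 16 of 17 members lower with a median of -0.22, and Opalin, a myelin protein (-0.70 ± 0.19), fell when adjusted over the list alone (adjusted p = 0.521 with an estimated correlation). Vascular and mural genes had 13 of 16 members lower with a median of -0.24, and Kdr and the pericyte gene Rgs5 (-0.39 ± 0.10) fell when adjusted over the list alone (adjusted p = 0.521 with an estimated correlation). Choroid plexus and ependyma genes, which mark tissue of the ventricle next to the dissection, had 14 of 15 members lower with a median of -0.78 (adjusted p = 0.521 with an estimated correlation). This list's mean ranged from 0.31 to 5.43 log2 CPM among the trained libraries, and replicates 5 and 16 held the 2 lowest of all 15 values. Slc4a5, a choroid plexus transporter, had -1.13 ± 0.69 (-1.82 without trained control replicate 10).

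The other lists called by camera with training were the unfolded protein response (22 of 23 higher), complement (13 of 14), cytokines (18 of 21), microglia (13 of 16) and the immunoproteasome (6 of 7) on the higher side. On the lower side were glutamate receptors (31 of 38), CA2 and CA3 neurons (12 of 12) and cortex (10 of 12). Their adjusted p with an estimated correlation ran from 0.360 for CA2 and CA3 neurons to 0.565 for microglia. The ubiquitin system list had no common direction, at 14 genes higher and 16 lower, and its median changed sign with the scaling of the libraries. CA1 pyramidal neuron genes had a median of 0.09 while camera gave them the lower direction, and they were not called.

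**Figure D3:**
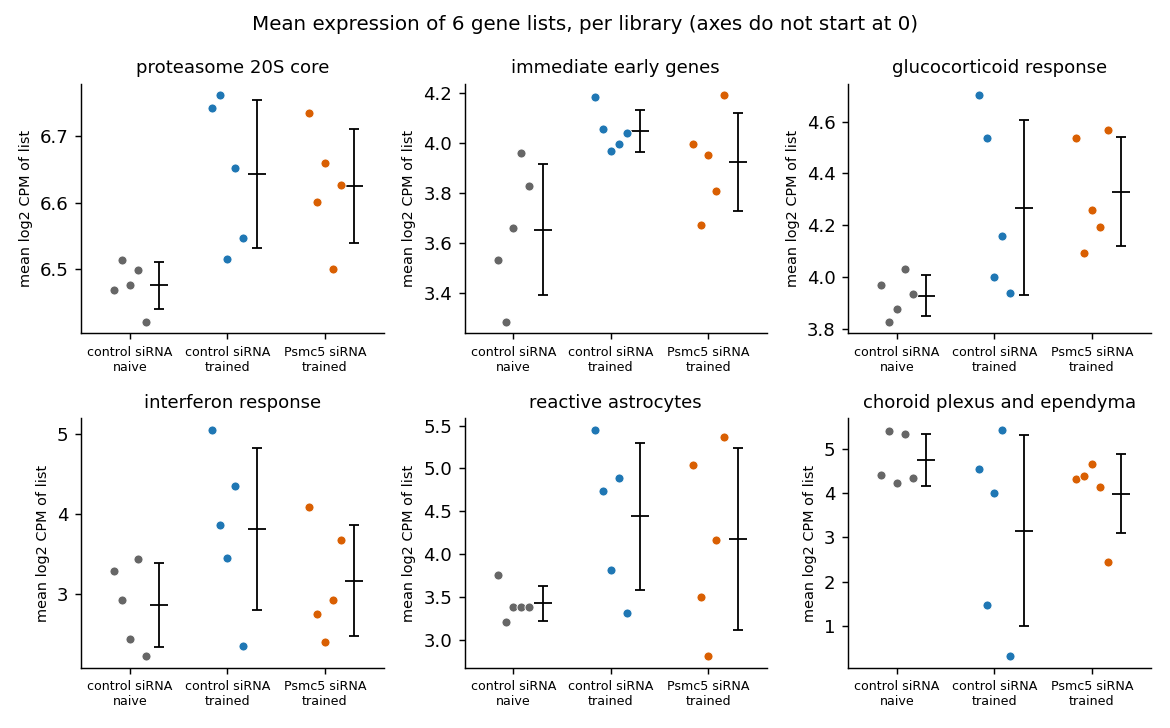
Mean log2 CPM of the measured members of 6 gene lists in each library (vertical axes do not start at 0); points are libraries, and the bars beside them give the mean and SD (n = 5). The 20S core and immediate early gene lists of the trained controls lie above those of all naive libraries, and the interferon, reactive astrocyte and choroid plexus lists spread widely among trained libraries, the last from 0.31 to 5.43.

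The second comparison asked what Psmc5 siRNA changed in trained rats. No gene passed the test between the libraries labelled Psmc5 siRNA and the trained controls. By edgeR 0 of 16272 genes had an adjusted p under 0.05, and the smallest was 1.00. By DESeq2 0 passed, with a smallest adjusted p of 0.485, and by limma voom 0 did. At an unadjusted edgeR p under 0.05 there were 298 genes, 210 higher and 88 lower, fewer than the 813.6 expected with no difference. Genes changed 2-fold in data simulated with the same depths and spread were called in 56% of cases in this comparison, genes changed 1.5-fold in 40% and those with the smallest simulated change in 8%.

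The 10 genes with the smallest p, none past the threshold, included Capn5 (log2 fold change 0.26 ± 0.06, from 50.1 to 60.0 CPM), whose naive mean was 63.1 CPM. Capn5 was also chosen by a small p for training, and the trained controls enter both comparisons. A low mean in those libraries alone gives opposite signs, so no return toward the naive level can be read from it. Rit1, a small GTPase, had 0.22 ± 0.06, and Mlxip, a glucose-responsive transcription factor, had 0.32 ± 0.09. Fam214b had 0.17 ± 0.05 and RGD1565616 0.28 ± 0.08. The other 5 had means under 2 CPM in each group: Rec114 (1.45 ± 0.40), Spata32 (1.20 ± 0.35) and the clone-named AABR07043453.1 (0.84 ± 0.19), AABR07004992.1 (1.09 ± 0.25) and AY172581.10 (-0.70 ± 0.21).

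Of the 40 lists, 7 rose and 13 fell under Psmc5 siRNA by camera at its preset correlation, and 0 did with an estimated correlation, by fry or by exact permutation of library means. The unadjusted counts at p under 0.05 in those 3 tests were 0, 0 and 1. With groups of 5 the permutation could hardly call a list after adjustment, so its 0 decides little. Interferon response genes had 29 of 32 members lower with a median of -0.62 (adjusted p = 0.648 with an estimated correlation), and 0 passed when adjusted over the list alone. Oas1a had -1.71 ± 0.53, Isg15 -1.33 ± 0.45, Usp18 -1.49 ± 0.53 and Oas2 -1.94 ± 0.68. The trained controls were highest in replicates 15 and 10, which stood apart on the first principal component (Isg15 36.1 and 34.3 CPM), while replicate 5 had less Oas1a (1.52 CPM) and Oas2 (0.468 CPM) than any Psmc5 siRNA library. Without the 4 libraries apart Oas1a had -1.18, Usp18 -1.04 and Oas2 -1.42. The list means of the groups overlapped, at 3.16 ± 0.69 and 3.81 ± 1.01 log2 CPM (n = 5; exact permutation p = 0.270). The 19S regulatory particle had 19 of 19 genes lower by a median of -0.05 (adjusted p = 0.717 with an estimated correlation), and Psmd13 had -0.10 ± 0.06. Immediate early genes had 29 of 38 members lower with a median of -0.11 (adjusted p = 0.648 with an estimated correlation), and Junb had -0.26 ± 0.13. Heat shock and protein folding genes had 21 of 23 members lower with a median of -0.06 (adjusted p = 0.648 with an estimated correlation), and Hsph1 had -0.14 ± 0.11. In each of these 4 lists 0 genes passed when adjusted over the list alone.

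Late activity response genes, which follow the immediate early genes, had 20 of 24 members lower with a median of -0.08 (adjusted p = 0.648 with an estimated correlation). Their library means were 4.25 ± 0.05 log2 CPM under Psmc5 siRNA and 4.43 ± 0.05 in trained controls without overlap (exact permutation p = 0.00794, the smallest that can occur, and 0.317 after adjustment over the 40 lists). Pdyn, the dynorphin precursor, had -0.75 ± 0.37, and 0 members passed when adjusted over the list alone. Interneuron genes had 17 of 19 members lower with a median of -0.16 (adjusted p = 0.717 with an estimated correlation). Slc32a1, the vesicular GABA transporter, had -0.34 ± 0.15, and Gad1, which makes GABA, had -0.33 ± 0.17. CA1 pyramidal genes had 9 of 9 members lower with a median of -0.29 (adjusted p = 0.760 with an estimated correlation), Wfs1 among them at -0.79 ± 0.43. Trained control replicate 6 had 1047 CPM of Wfs1, and the other trained controls 137 to 542 CPM. The Psmc5 siRNA libraries had 192 to 519 CPM and the naive libraries 199 to 609 CPM, so the groups overlapped. Blood cell genes had 6 of 6 members lower with a median of -0.67 (adjusted p = 0.648 with an estimated correlation), with Hba-a2 at -0.80 ± 0.63 (-1.90 without Psmc5 siRNA replicate 13), and the vascular list had 13 of 16 lower with a median of -0.09 (adjusted p = 0.760), Kdr among them at -0.27 ± 0.11.

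On the higher side under Psmc5 siRNA, thalamus genes had 11 of 12 members higher with a median of 0.32 (adjusted p = 0.753 with an estimated correlation), Prkcd among them at 0.61 ± 0.45, and oligodendrocyte genes had 16 of 17 higher with a median of 0.13 (adjusted p = 0.815). Presynaptic vesicle genes had 22 of 27 members higher with a median of 0.07 (adjusted p = 0.818 with an estimated correlation). Rims2 had 0.30 ± 0.13 and Rims1 0.29 ± 0.15. Homer3, a postsynaptic scaffold, had 0.32 ± 0.10, in a glutamate receptor list that was not called at 18 genes higher and 20 lower. The choroid plexus list was called as higher, with library means 0.84 above the trained controls, while its median log2 fold change was -0.03 and its mean -0.08, with 4 genes higher and 11 lower (adjusted p = 0.818 with an estimated correlation). Cortex (11 of 12), oligodendrocyte precursors (8 of 10) and CA2 and CA3 neurons (8 of 12) were the other lists on the higher side. The unfolded protein response (17 of 23), dentate granule neurons (11 of 13), reactive astrocytes (11 of 18) and the ubiquitin system (19 of 30) were the others on the lower side. By camera with an estimated correlation no list of this comparison had an adjusted p under 0.648. The count of lists fell from 20 to 13 without trained control replicate 16 or without Psmc5 siRNA replicate 17, to 12 with the main axis of cell type markers as a covariate and to 11 with the choroid plexus list as one.

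A further question was whether genes that responded to training moved back under Psmc5 siRNA. Of the 200 genes with the smallest p for training, 86.5% had the opposite sign under Psmc5 siRNA, and the share ran from 68.0% to 96.5% when 1 library was left out. The trained controls enter both comparisons, which alone makes signs opposite: in 20 simulations with no effect of either treatment, 92.1% ± 1.79 (SD) of the top 200 genes had opposite signs. In 100 relabelings of the 15 libraries the mean was 89.6%. With the trained controls split 2 and 3 between the comparisons, the share was 37.9% on average over 20 splits, with a range of 11.6% to 69.5%. Across all genes, which are not independent replicates, the fold changes had a covariance of -0.0268 against -0.0306 in the simulations, a difference of 0.00384, and 0.0168 with the controls split. No reversal of the training response beyond that of the shared libraries was measured.

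**Figure D4:**
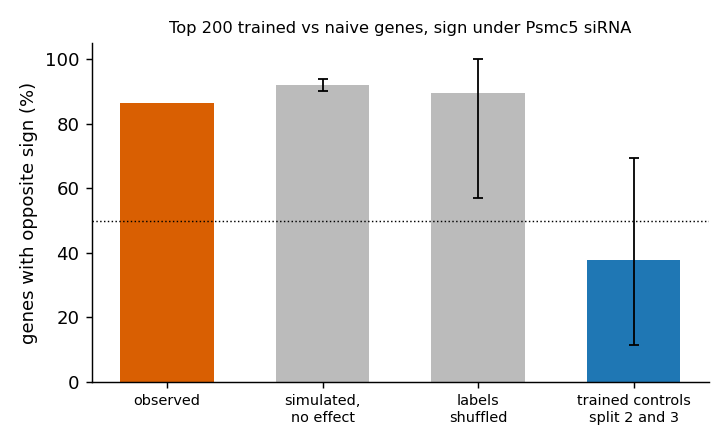
Share of the 200 genes with the smallest training p that had the opposite sign under Psmc5 siRNA (vertical axis, percent from 0). The observed 86.5% is below the 92.1% of 20 simulations with no effect (error bar, SD) and the 89.6% of 100 relabelings (bar, central 95%), and above the 37.9% mean of 20 splits of the trained controls (bar, range); the dotted line marks 50%.

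The third comparison set trained rats with Psmc5 siRNA against naive rats with control siRNA, so that training and siRNA differ together. DESeq2 called 10 genes higher and 11 lower, and 10 of these are given here with log2 fold changes and SEs from the edgeR fit. Kdr fell to 10.2 ± 1.71 CPM from 17.5 ± 1.16 (log2 fold change -0.78 ± 0.11), and so did Clec14a (-0.80 ± 0.15), an endothelial lectin, Dll4 (-0.98 ± 0.21), a Notch ligand, and Edn1 (-0.84 ± 0.17), the endothelin 1 precursor. These 4 genes were picked from the calls and do not make up a tested group. Kdr, Clec14a and Dll4 were also called lower by DESeq2 in trained controls against naive libraries. Slc22a8 (-0.61 ± 0.11) and Bcam (-0.51 ± 0.10), a laminin receptor, were also lower. Ddit4 (0.54 ± 0.09), Per1 (0.85 ± 0.15), Ccdc117 (0.44 ± 0.09) and AC125248.1 (2.86 ± 0.61) were higher. All 5 Psmc5 siRNA libraries lay on the same side of the naive median for each of these 10 genes, which their choice from the calls makes likely. By edgeR's quasi-likelihood test 0 of 16272 genes had an adjusted p under 0.05, and Kdr had the smallest at 0.0777. The edgeR count at an unadjusted p under 0.05 was 1323, with 971 higher and 352 lower. Kdr passed edgeR's test without trained control replicate 15 (adjusted p = 0.0481) or Psmc5 siRNA replicate 13 (0.0127), and Per1 passed without naive replicate 9 (0.0294). Over all settings the adjusted p of Kdr ran from 4.98e-07 with DESeq2 to 0.371, and that of Per1 from 4.94e-04 to 0.896. With limma voom 0 genes passed, and with sample quality weights 1 did, Kdr (adjusted p = 0.0103).

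By camera at its preset correlation 13 lists rose and 8 fell, against 0 with an estimated correlation, 0 by fry and 0 by exact permutation of library means, with 1, 3 and 4 lists at an unadjusted p under 0.05. The permutation could again hardly call a list with groups of 5. Glucocorticoid response genes had 19 of 23 members higher with a median of 0.37 (adjusted p = 0.372 with an estimated correlation). Adjusted over the list alone, 5 rose, among them Ddit4, Per1, Sgk1, a kinase (0.89 ± 0.26), and Cebpd (0.92 ± 0.31). Without the 4 libraries apart on the first principal component Cebpd had 0.30, while Sgk1 had 0.87, Ddit4 0.55 and Per1 0.82. The list mean was 4.33 ± 0.21 log2 CPM against 3.93 ± 0.08 in naive libraries without overlap (n = 5; exact permutation p = 0.00794, and 0.317 adjusted over the lists). The 20S core again had 13 of 13 genes higher with a median of 0.16 (adjusted p = 0.680 with an estimated correlation), and 4 rose when adjusted over the list alone, among them Psma5 (0.26 ± 0.07) and Psmb2 (0.20 ± 0.06). Ribosomal protein genes had 61 of 61 members higher with a median of 0.22, of which 0 passed when adjusted over the list alone (adjusted p = 0.680 with an estimated correlation), and Rps2 had 0.37 ± 0.13. Immediate early genes had 28 of 38 members higher with a median of 0.26 (adjusted p = 0.680 with an estimated correlation), and Egr2 (1.51 ± 0.39) and Fos (0.96 ± 0.33) did not pass when adjusted over the list alone.

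Vascular and mural genes had 15 of 16 members lower with a median of -0.32 (adjusted p = 0.680 with an estimated correlation). Adjusted over the list alone, 6 fell, among them Kdr and the pericyte genes Rgs5 (-0.30 ± 0.10) and Pdgfrb (-0.33 ± 0.12), and the smooth muscle gene Tagln rose (1.84 ± 0.67), though without Psmc5 siRNA replicate 7, with 360 CPM, its value was 0.95. Infiltrating immune cell genes had 12 of 13 members higher with a median of 1.24 (adjusted p = 0.680 with an estimated correlation), and 6 rose when adjusted over the list alone, among them Mrc1 (2.31 ± 0.66) and Lyve1 (1.70 ± 0.52), markers of border macrophages, Cd8a (2.68 ± 0.86) and S100a9 (2.39 ± 0.74). The list mean ran from 0.64 to 3.68 log2 CPM among these 5 libraries, and without replicate 7, the highest, Lyve1 had 0.98 and Cd8a 2.03. Reactive astrocyte genes had 18 of 18 members higher with a median of 1.03 (adjusted p = 0.680 with an estimated correlation). Lgals3 (2.51 ± 0.75) and Timp1 (2.05 ± 0.61) were among the 3 that rose when adjusted over the list alone. Replicates 13 and 7, which stood apart on the first principal component, had list means of 5.04 and 5.37 against 2.80 in replicate 19, and without the 4 libraries apart Lgals3 had 0.78 and Timp1 0.81. Without replicate 7 alone Lgals3 had 1.79. Hmox1, in the heat shock list, had 3.11 ± 0.95 without passing (2.44 without replicate 7, 1.27 without the 4 libraries apart). Interneuron genes had 19 of 19 members lower with a median of -0.22 (adjusted p = 0.680 with an estimated correlation), with Slc32a1 at -0.41 ± 0.15 and Gad1 at -0.38 ± 0.17, and Slco1c1, a thyroxine transporter in the astrocyte list, had -0.48 ± 0.14. The number of called lists was 8 without the 4 libraries that stand apart on the first principal component and 13 with the reactive astrocyte list as a covariate, both chosen after seeing the data.

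The genes called by DESeq2 in the 2 comparisons with naive libraries overlapped. Of 23 and 10 genes that rose, 6 were shared, and of 29 and 11 that fell, 5 were shared. Both comparisons use the same naive libraries, and the overlap that these alone would give was not computed. Of the top 200 genes for training 100% had the same sign in the comparison of Psmc5 siRNA with naive libraries, against 92.3% in the simulations with no effect. With the naive libraries split 2 and 3 between the comparisons the share was 75.5% on average over 20 splits, with a range of 59.6% to 88.8%. The covariance of fold changes across genes was 0.121 against 0.0313 simulated and 0.0363 on average in the relabelings, and 0.106 with the naive libraries split.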

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

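The tests of the 3 patterns and the splits for genes past the adjusted threshold were chosen after the results were seen, while the splits for unadjusted counts, for lists and for the share of opposite signs were chosen before. Of 345 groups of 5 values examined (library totals, Psmc5, 40 list means and the genes named), 23 held a value far from its group, where chance gives about 17.25. A value counted as far when its gap to the nearest other was above 0.71 of the group's range.

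The libraries labelled Psmc5 siRNA showed no loss of Psmc5 RNA. The lowest trained control stood at 89.1% of the naive mean and the lowest of all 15 libraries at 84.8%. A swap of labels between the trained groups cannot be told apart from correct labels, since without a loss of Psmc5 RNA in any library a swap leaves no mark on it. A knockdown in a part of the cells, diluted by the rest of the tissue, cannot be told apart from no knockdown, since the interval of the fold reached down to 0.857 and no cells were separated. RNA that had recovered by the time of dissection, or an effect on protein alone, was not tested.

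Reactive astrocyte genes were higher in 7 of the 10 trained libraries than in any naive library. A lower share of neurons would raise the markers of every other cell type alike. Against that, the reactive astrocyte list minus the mean of the astrocyte and oligodendrocyte lists was 1.16 (log2) higher in trained controls than in naive libraries (exact permutation p = 0.0159). The same difference for Psmc5 siRNA against naive libraries was 0.83 (exact permutation p = 0.127), and for both trained groups against naive libraries it was 0.99 (exact permutation p = 0.0276). The oligodendrocyte list was itself lower in trained controls (median -0.22), which adds to the difference. The reactive astrocyte list was picked for its values in these libraries, so these p-values are biased toward small values. Tissue injury at surgery that differed between animals may also be the source and cannot be told apart from training in these data, since no measure of injury comes with the 7 libraries, and training itself stays open as well.

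Kdr, Clec14a, Dll4 and Edn1 had a median log2 fold change of -0.82 between Psmc5 siRNA trained and naive libraries. Fewer endothelial cells as the whole cause would lower the 8 measured endothelial members of the vascular list by as much, and their median was -0.35 with an SD over members of 0.20. Kdr is in both sets, and without it the medians were -0.84 for the 3 other genes and -0.34 (SD 0.13) for the 7 other members. The 4 genes were picked for their change, which widens that gap. All 8 members were lower, so a smaller loss of endothelial cells stays open for a part of the difference. A response of these cells to training or to the siRNA stays open as well. In trained controls against naive libraries the median was -0.56 for the 4 genes and -0.24 for the 8 members. A part of the lower level was therefore present without Psmc5 siRNA. A scaling error would move all genes of a library alike. Between Psmc5 siRNA trained and naive libraries the median of the 4 genes was -0.82, -0.83 and -0.80 with TMM, DESeq2 size factors and library totals only. The median of all genes was -0.00382, -0.0166 and 0.0188. These values argue against scaling as the cause of the lower level of the 4 genes relative to other genes. The choice among the scalings was a weak test by itself, since they moved the median of all genes by no more than 0.0227.

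Trained control replicate 15 had a total of 54.4 in units of 1e6 counts, above the other 4 at 44.7 to 46.7. Trained control replicate 10 was low for the ubiquitin system list (6.84 log2 CPM against 6.98 to 7.03) and high for meningeal fibroblast genes (4.91 against 3.63 to 3.95). Its Spock1 was 96.2 CPM and its S100a9 5.45 CPM, both the highest of their group. Naive replicate 1 was high for late activity response genes (4.71 against 4.25 to 4.26), and naive replicate 2 was low for the unfolded protein response (5.16 against 5.23 to 5.24). Psmc5 siRNA replicate 13 was high for the blood cell list (6.20 against 2.85 to 3.74), with Hba-a2 at 374 CPM and Hbb at 630 CPM, and low for Capn5 at 52.8 CPM. Psmc5 siRNA replicate 7 was low for the choroid plexus list (2.44 against 4.14 to 4.66), with B3gnt2 at 25.1 CPM and Tagln at 360 CPM, both the highest of their group.

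Naive replicate 11 held the highest naive values of Timp1 (9.28 CPM), Gfap (4341 CPM), Rps2 (442 CPM), Cebpd (12.5 CPM) and Mrc1 (5.98 CPM). Homer3 was highest in naive replicate 12 (79.2 CPM) and Ccdc117 in naive replicate 9 (14.9 CPM). AABR07043453.1 was lowest in trained control replicate 6 (0.70 CPM), and Spata32 was highest in Psmc5 siRNA replicate 19 (0.563 CPM).

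For the 0 genes past the edgeR threshold the splits decide nothing, since any count reaches 0 and so all 100 splits did, with highest other counts of 12, 4343 and 1 in the 3 comparisons. The 52 and 21 genes called by DESeq2 were not set against splits. For the other 6 counts and for the share of genes with opposite signs, chance could not be excluded by regrouping the same libraries. The 1709 genes at an unadjusted p under 0.05 with training were reached by 13 of 100 splits (highest other 3799), the 298 under Psmc5 siRNA by 78 (highest other 6439) and the 1323 of the third comparison by 15 (highest other 3040). The 23 called lists with training were reached by 12 of 100 splits (highest other 27), the 20 under Psmc5 siRNA by 26 (highest other 26) and the 21 of the third comparison by 34 (highest other 26). The share of 86.5% with opposite signs was reached by 76 of 100 relabelings, the highest other being 100%. A split of the 10 trained libraries that called 4343 genes points to a structure among them other than the siRNA.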

How the results depend on the processing

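Settings chosen beforehand were run together with some chosen after seeing the data (the 2 left-out sets of libraries, the list covariates, permutation of list means). The 96 named gene values had 2780 alternative values (Psmc5 is not among them and follows separately). Of these alternatives 2746 kept direction and side of the threshold, 34 kept direction and passed it, and 0 reversed. None of the named values was past the threshold in the main fit, so none could lose it, and choice by a small p makes a kept direction likely. Size was not counted: without the 4 libraries apart on the first component Lgals3 went from 2.51 to 0.78 in the third comparison. The cause of the changes below was not tested unless stated.

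Genes past the threshold moved from 0 with DESeq2 to 52 for training and 21 for Psmc5 siRNA trained against naive, where quality weights, an adjusted p under 0.1 and the loss of the 4 libraries apart on the first component each gave 1. Without the 2 libraries with few choroid plexus transcripts training gave 1. Leaving out 1 library gave 0 to 1 with training, 0 to 0 under Psmc5 siRNA and 0 to 1 in the third comparison.

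The log2 fold change of Psmc5 was 0.0286 with the cell type component as covariate, 0.0244 with the choroid plexus list and 0.121 without the 2 libraries, against -0.0143 with an SE of 0.10. Without the 4 libraries apart on the first component it was -0.142, on the side of a loss. Leaving out 1 library gave -0.0691 to 0.0690.

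Lists past the threshold went from 23, 20 and 21 to 0, 0 and 0 with an estimated correlation, with fry and with permutation of list means. These tests take the correlation between genes into account. For the permutation the counts of 0 decide little, since with groups of 5 a list alone cannot have an adjusted p under 0.317. Under Psmc5 siRNA the count was 12 with the cell type component and 11 with the choroid plexus list as covariate. In the third comparison it was 13 with the reactive astrocyte list and 8 without the 4 libraries. Leaving out 1 library gave 22 to 27, 13 to 26 and 15 to 24.

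The share of genes with opposite signs was 37.9% with the trained controls split, because no library then enters both comparisons. It was 96.5% without the 4 libraries, 97.5% without the 2, and 68.0% to 96.5% without 1 library.

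List medians kept their sign under the 3 scalings except the ubiquitin system with training and dentate granule neurons, housekeeping and oligodendrocyte precursors in the third comparison. No paired analysis was possible because the groups share no replicate numbers.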

Other observations

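The test of 4 lists in both trained groups was chosen before its own result was seen, while the exact permutation of list means within a comparison was chosen after seeing the data. Several lists had median changes of 0.10 or less in all 3 comparisons. Astrocyte genes had medians of -0.05, -0.06 and -0.05, mitochondrially encoded genes -0.07, -0.01 and -0.10, nuclear genes of oxidative phosphorylation 0.04, -0.02 and 0.02, chromatin modifiers 0.02, 0.05 and 0.04, and circadian clock genes -0.05, 0.02 and -0.06 (log2 fold change for training, for Psmc5 siRNA, and for Psmc5 siRNA trained against naive). None of these lists was called by camera in any comparison, which does not show that they were unchanged. Chromatin modifiers had library means of 5.35 ± 0.03 log2 CPM in Psmc5 siRNA trained and 5.30 ± 0.02 in naive libraries (n = 5; exact permutation p = 0.0238, and 0.317 adjusted over the lists). Per1 was the exception among clock genes and passed when adjusted over that list alone in both comparisons with naive libraries. Antigen presentation genes had medians of 0.20, 0.48 and 0.88 and were not called either.

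The first principal component held 36.8% of the variance and followed genes such as Hmox1, Cxcl1, Msr1 and Ccl7, named after their loadings were seen. The 5 naive libraries scored between -31.9 and -6.40 on it. The trained controls scored from -27.8 to 47.3 and the Psmc5 siRNA libraries from -33.6 to 58.1.

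With both trained groups pooled against the naive libraries, edgeR called 0 genes at an adjusted p under 0.05 (smallest 0.0617, for Kdr and Slc22a8), and 1992 had an unadjusted p under 0.05. DESeq2 was not run on this grouping. A hypothesis was that a response to training shared by both trained groups raises the immediate early gene, glucocorticoid response, heat shock and 20S core lists. These 4 lists were picked for their values in the same 15 libraries, so the test cannot decide for or against the hypothesis, and its p-values are biased toward small values by that choice. The exact permutation test of 10 against 5 library means (3003 regroupings) gave unadjusted p-values of 0.00666, 0.00966, 0.00833 and 0.00400, and each came to 0.0966 after adjustment over 40 lists, so 0 of the 4 passed. The 20S core mean was 0.16 (log2) higher and lay above the highest naive library in 9 of 10 trained libraries, the immediate early genes 0.33 in 7, the heat shock genes 0.32 in 9 and the glucocorticoid response 0.37 in 8. The heat shock mean leaned on few members. Its list medians were 0.09 and 0.06 in the 2 comparisons with naive libraries, where Hmox1 had 3.41 and 3.11. Whether the trained groups share a response of these 4 lists cannot be told from these libraries.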
